A study of Mus musculus with 19 samples.

How the data were processed

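RNA was measured in 19 samples of whole mouse liver, each hybridised to 1 Affymetrix array with 1 colour. The sample titles put the animals in 6 groups, made of 3 genotype codes (WT, KO and TG) and 2 diets, a normal diet (ND) and a high-fat diet (HFD). Each group had 3 arrays except TG on HFD, which had 4. The labels do not spell out the genotype codes, and Kcp is named only in the title of the series. They give no sex, strain, litter, batch or time of harvest. Animal numbers differ in style by diet and mostly cluster by genotype, so neither can be told apart from cohort. Each title carries its own animal number, and replicates were taken as separate animals on that basis alone.

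The deposited table holds log2 values per probe set, which the authors had normalized between arrays before deposit. The submitters' processing notes name affy, RMA and limma with no version, role or order. The log base and the use of RMA, which includes background correction and quantile normalization, were inferred from those names and from the range of the values, and neither is stated in the sources used here. If the base were another, every log2 difference given here would scale by 1 factor, while tests and directions would be kept. Array medians lay between 0.983 and 1.075, and 1.81% of all values were below 0. Arrays have no read depth, and the number of animals limits the precision of each group mean.

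The platform annotation pairs 23521 of the 41345 probe sets with 1 gene symbol, 1814 with several and 16010 with none here. Symbols were checked through Entrez identifiers against a RefSeq gene table of the assembly GRCm38.p6, where 23328 of the 23521 matched and no symbol needed a change. Probe sets with several symbols or none were kept out of the gene results. Where a symbol had more than 1 probe set, as for 1082 symbols, the probe set with the highest mean over all arrays stood for the gene, which left 22180 genes. No filter on dim genes was applied. Of these genes 56.5% had a mean log2 value below 2, a range in which background can make differences look smaller.

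All 19 arrays were fitted in 1 linear model of the 6 group means with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 13 residual and 4.76 prior degrees of freedom. From it came 9 comparisons of 2 groups and 2 interactions, each being the diet effect in KO or TG minus that in WT. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 are said to have changed. Adjusted p-values of genes are from this limma model throughout, are two-sided, and stand beside log2 differences and their moderated standard errors (SE). Standard deviations (SD) are those between the arrays of a group.

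Before the data were examined, 45 gene lists were fixed, covering metabolic pathways, stress and immune responses, BMP and TGF-beta signalling, the circadian clock, sex-biased liver genes and markers of liver, blood and neighbouring cell types. The 43 lists of at least 5 measured genes used for testing were compared with all other genes by camera from limma with a preset correlation between genes of 0.01, adjusted over the 43 lists in each comparison. The same test was repeated with the correlation estimated from the list itself. A clock score was taken per array as the mean of 10 clock genes that peak towards evening minus the mean of 5 that peak towards morning, and was compared between groups by two-sided exact permutation tests. The phase of each clock gene was written down as textbook knowledge after the first results were seen.

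Genes were named by a rule fixed in advance. For each comparison of 2 groups it takes, among genes with an adjusted p under 0.05 and no overlap between the arrays of both groups, the 8 largest rises and the 8 largest falls, or 5 and 5 for KO against TG. It adds up to 4 members with the smallest p of each list that passed, the 8 genes of smallest p for each interaction, and fixed genes whatever their value. The fixed genes reported here were Kcp, Id1, Hamp and Smad7 for genotype, with 1 other not reported here, and Cd36, Cidea, Cidec, Scd1, Fasn, Cyp7a1, Fgf21, Pparg, Col1a1 and Tnf for diet. Predicted genes, small RNAs and pseudogenes were counted and not named, apart from neighbouring genes that the closing section singles out after their values were seen. The text names a selection of the genes that the rule takes.

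Comparisons that share a group were set beside 20 simulated data sets in which no group differed, and beside the overlap that independent lists would have. The procedure was tested on simulated data with 50 genes changed at each of 4 sizes among 22180. The changed genes were drawn from those with a mean log2 value of at least 2, so that recovery of dimmer genes was not measured. For KO against WT on ND it recovered 6%, 76%, 100% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 2 false calls. For TG against WT on HFD the shares were 16%, 88%, 100% and 100%, with 8 false calls. A list raised as a whole was found, and 0 of 40 unchanged lists were called by camera. The simulated genes varied independently, so that this does not measure false calls of lists whose genes vary together.

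Counts of genes and the differences of named genes were computed again with cyclic loess between arrays, with arrays centred on their medians, without the dimmest 40% of genes and without each array in turn. They were also repeated with a trended and robust variance prior, with array weights, with the mean of all probe sets of a gene and with the compared arrays alone. Gene lists were repeated with the first 4 of these settings and with the estimated correlation, and overlaps only at an adjusted p of 0.10. After the data had been seen, a repeat without 2 arrays was added for counts, genes and lists, and one with the clock score as a covariate for counts and genes. The slope of that covariate is estimated from the spread of the score within groups. Differences that stay in that repeat are therefore not shown to be free of clock phase. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.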

Results

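Expression of 22180 genes was measured in the livers of 19 mice aged 2 to 3 months, kept for 4 weeks on a normal diet (ND) or a high-fat diet (HFD). The title of the series names the Kielin/chordin-like protein, Kcp, a secreted protein with cysteine-rich domains that acts on BMP and TGF-beta signalling. Its design text states that all genotypes and diets were compared with each other. Arrays of 1 group correlated with r between 0.968 and 0.9793 across all 41345 probe sets. The array of WT HFD replicate 1 had the lowest mean correlation with its own group, 0.9688, and with the other groups, 0.9633, and TG HFD replicate 2 the next lowest with the other groups, 0.9651. All animals had the expression of males, with Xist between 0.16 and 1.23 and the Y-linked Eif2s3y between 6.09 and 6.93, Uty between 5.33 and 6.05 and Kdm5d between 4.09 and 5.07 (log2, 19 arrays). In a principal component analysis of 9657 genes, the first component, with 24.2% of the variance, set the TG arrays apart from all others. Genes of families with near-identical copies, such as Serpina1, Mug, Mup, Cyp2b, Cyp2c, Cyp4a and immunoglobulin genes, can share probes, so that a value may belong to another copy.

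Kcp itself was high in the TG livers. Its mean was 5.56 ± 0.19 in TG on ND (SD, n = 3) and 5.66 ± 0.13 in TG on HFD (SD, n = 4), against 2.55 ± 0.23 and 2.23 ± 0.40 in WT (SD, n = 3 each). The difference from WT was 3.01 on ND (SE 0.20, adjusted p = 4.54e-08) and 3.43 on HFD (SE 0.18, adjusted p = 4.05e-09). In KO livers Kcp averaged 2.03 ± 0.34 on ND and 2.01 ± 0.14 on HFD (SD, n = 3 each), and the difference from WT did not pass on either diet (-0.52, adjusted p = 0.215, and -0.22, adjusted p = 0.844). KO arrays lay between 1.64 and 2.30 and WT arrays between 1.77 and 2.82, levels at which most genes of the array are dim. Kcp has 1 probe set, and where its probes lie relative to the deleted part is not known here, so that these values do not check the KO label.

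**Figure D1:**
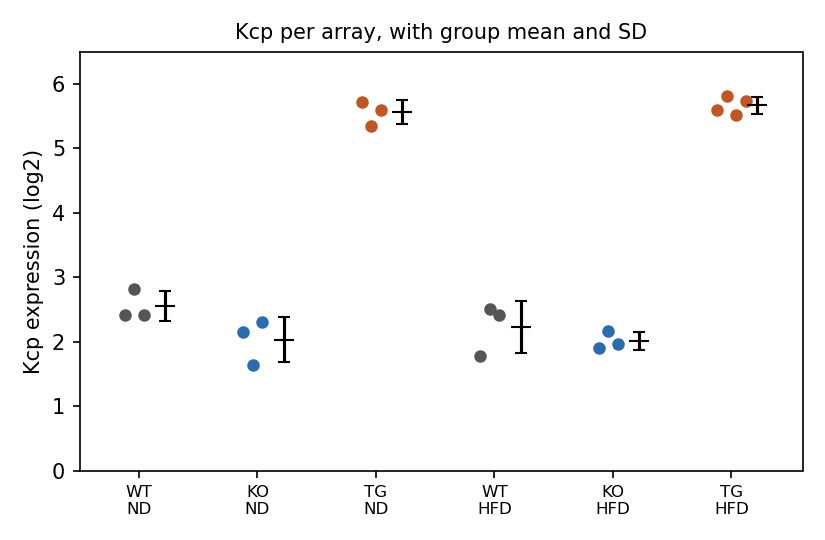
Kcp expression (log2) in each of the 19 arrays by genotype and diet, with the mean and SD of each group beside the points. The TG groups average 5.56 and 5.66, and all other groups lie between 2.01 and 2.55.

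The first question was which genes differed between TG and WT livers on the normal diet. Macrophage markers were higher in TG, and acute-phase proteins passed as higher with a preset correlation only (adjusted p = 0.209 with an estimated correlation). Marco, a scavenger receptor of macrophages, rose by 3.21 (SE 0.39, adjusted p = 0.000147), and the Kupffer cell receptor Clec4f by 1.43, the CSF1 receptor Csf1r by 1.54 and Cd68 by 1.78 (adjusted p = 0.000561 or lower in each). Of 24 markers of Kupffer cells and macrophages 13 rose and 11 did not pass, with a median difference of 1.14 (camera adjusted p = 1.95e-23, and adjusted p = 0.0199 with an estimated correlation); 14 rose when adjusted over the list alone. The metal-binding metallothioneins Mt2 (4.75, SE 0.64) and Mt1 (3.51) and the siderophore-binding Lcn2 (3.73) led the acute-phase proteins. Of 23 genes on that list 4 rose, or 10 adjusted over the list alone (median 0.50, camera adjusted p = 6.79e-13, lost at adjusted p = 0.209 with an estimated correlation). Other large rises were the aspartic protease Ctse (5.11, SE 0.33), the glutathione transferase Gstp3 (4.29), the complement component C4a (3.82), the peptidase Mme (3.62) and Zfp872 (3.79). Zfp872 lost its call without 5 of the 6 arrays (highest adjusted p 0.177, without TG ND replicate 3). Ctse and Mme were also higher than in WT on ND in KO on ND (4.40 and 4.96) and in WT on HFD (6.51 and 4.66).

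Interferon-response genes were also higher in TG on ND, with 6 of 26 rising, or 8 adjusted over the list alone (median 0.42, camera adjusted p = 3.72e-09, and adjusted p = 0.0396 with an estimated correlation). They included Bst2 (2.25, SE 0.27), which tethers virus particles at the cell surface. Irf7, Stat2 and Mx2 also passed but lost their calls without 5, 5 and 4 of 6 arrays (highest adjusted p 0.0859, 0.104 and 0.129). Among inflammatory cytokines and chemokines 3 of 24 rose, or 7 adjusted over the list alone (median 0.36, camera adjusted p = 5.23e-07, and adjusted p = 0.0363 with an estimated correlation). Of these Il1b (1.64) lost its call without 3 of 6 arrays (highest adjusted p 0.0919), the B cell chemokine Cxcl13 (2.57) without 5 (0.213) and Vcam1 (1.09) without all 6 (0.257). Both lists moved together with the macrophage markers, whose median difference was 1.14. T and NK cell markers had a median of 0.18 (camera adjusted p = 0.0279, and 0.11 without TG ND replicate 3) and neutrophil markers one of 0.16 (camera adjusted p = 0.0114, and 0.087 without TG ND replicate 1). Both calls were lost with the correlation estimated (adjusted p = 0.131 and adjusted p = 0.483 with an estimated correlation). Of 18 stellate cell and fibroblast markers 3 rose, or 4 adjusted over the list alone (median 0.35, camera adjusted p = 0.00025, adjusted p = 0.157 with an estimated correlation).

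Genes of cholesterol synthesis had a median of 0.67 in TG on ND, with 1 of 19 rising, or 6 adjusted over the list alone (camera adjusted p = 9.05e-11, lost at adjusted p = 0.258 with an estimated correlation). That gene was Sqle, squalene epoxidase (2.68), which lost its call without 5 of 6 arrays (highest adjusted p 0.146, without WT ND replicate 1). Xenobiotic-metabolising enzymes were lower (median -0.11, mean -0.46, camera adjusted p = 0.00133, adjusted p = 0.209 with an estimated correlation): Cyp2c55 fell by 3.13 (SE 0.34) and Cyp2c37 by 2.35, 2 of 23 members, or 3 adjusted over the list alone. Lipid droplet genes had a median of -0.23, with 2 of 19 falling, or 4 falling and 1 rising adjusted over the list alone (camera adjusted p = 0.00375, adjusted p = 0.288 with an estimated correlation). These were the droplet coat protein Plin3 (-0.74) and the fatty acid transporter Cd36 (-1.30), which lost its call without 4 of 6 arrays (highest adjusted p 0.0747). The largest falls also took in the lectin gene Clec2h (-5.06), the ion channel Asic5 (-3.76, SE 0.19), the exchange factor Tiam2 (-2.73), the protease inhibitor Mug2 (-2.27), the steroid hydroxylase Cyp17a1 (-3.18) and the drug exporter Abcb1b (-2.57). Cyp17a1 lost its call without 5 of 6 arrays and Abcb1b without 4 (highest adjusted p 0.122 and 0.117, both without WT ND replicate 1).

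In all, 289 genes differed between TG and WT on ND, 205 higher and 84 lower in TG, and in 288 of them the arrays of both groups did not overlap. Over all genes 15.8% did not overlap, where chance gives 10%. The count was 176, 180, 187 and 165 without WT ND replicate 2, WT ND replicate 3, TG ND replicate 2 and TG ND replicate 3, and 170 with the clock score as a covariate. The clock score itself differed by -0.67 between TG and WT on ND (two-sided exact permutation p = 0.4, where 3 arrays against 3 allow no p below 0.1).

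On the high-fat diet, 3 lists of fat metabolism passed as lower in TG than in WT, and each lost its call with an estimated correlation. The lipid droplet genes Cd36 (-2.31, SE 0.24, adjusted p = 3.17e-05), Mogat1 (-2.43), which makes diacylglycerol, Fitm1 (-2.40) and Plin3 (-0.98) fell. Of 19 genes on that list 8 fell and 1 rose, or 11 and 1 adjusted over the list alone (median -0.97, camera adjusted p = 7.37e-09, lost at adjusted p = 0.0577 with an estimated correlation). Among genes of fatty acid oxidation and PPARA targets 6 of 31 fell, or 16 with 1 rising adjusted over the list alone (median -0.36, camera adjusted p = 9.78e-12, lost at adjusted p = 0.198 with an estimated correlation). They included the fatty acid hydroxylase Cyp4a14 (-5.19, SE 0.99), the pantetheinase Vnn1 (-4.02) and the acyl-CoA thioesterases Acot3 (-2.56) and Acot4 (-1.90). Fatty acid and triglyceride synthesis had 4 of 24 genes lower, or 9 with 1 higher adjusted over the list alone (median -0.51, camera adjusted p = 1.01e-05, lost at adjusted p = 0.353 with an estimated correlation). These 4 were Elovl5 (-0.91), Agpat2 (-0.56), the stearoyl-CoA desaturase Scd1 (-1.08) and Pgd (-0.71), which lost their calls without 4 to 6 of the 7 arrays (highest adjusted p 0.138, 0.134, 0.164 and 0.170, all without WT HFD replicate 3).

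Macrophage genes were again higher in TG on HFD, with 15 of 24 markers rising, or 16 adjusted over the list alone (median 1.18, camera adjusted p = 4.04e-19, and adjusted p = 0.0361 with an estimated correlation). Marco rose by 3.75 (SE 0.36, adjusted p = 1.62e-05), the folate receptor Folr2 by 2.13, Csf1r by 1.55 and Clec4f by 1.42. Of the inflammatory list 4 of 24 genes rose, or 9 adjusted over the list alone (median 0.51, camera adjusted p = 4.65e-07, and adjusted p = 0.0361 with an estimated correlation), led by the adhesion molecule Vcam1 (1.83). Interferon-response genes had 4 of 26 higher, or 9 adjusted over the list alone (median 0.39, camera adjusted p = 1.41e-07, lost at adjusted p = 0.0577 with an estimated correlation), among them Bst2 (1.69), Irf7 (1.24) and Oas2 (1.64). Markers of T and NK cells (median 0.20), B and plasma cells (0.31) and neutrophils (0.38) also passed (camera adjusted p = 0.00895, 0.00725 and 0.00251), each lost with an estimated correlation (adjusted p = 0.0654, 0.251 and 0.360 with an estimated correlation). The neutrophil list was lost without TG HFD replicate 2 (adjusted p = 0.275). Among them the immunoglobulin heavy chain Ighm rose by 2.38 (SE 0.36) and the T helper cell marker Cd4 by 1.13, the latter losing its call without 6 of 7 arrays (highest adjusted p 0.113). Stellate cell and fibroblast markers (3 of 18 higher, and as many adjusted over the list alone, median 0.31) and extracellular matrix genes (1 of 29, and as many, median 0.22) passed as higher as well (camera adjusted p = 0.00245 and 0.00837). Both were lost with an estimated correlation (adjusted p = 0.198 and 0.353 with an estimated correlation), extracellular matrix also without TG HFD replicate 2 (adjusted p = 0.0892).

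Male-biased liver genes were higher on balance in TG on HFD, with 7 of 21 rising and 3 falling, or 12 and 3 adjusted over the list alone (median 0.55, camera adjusted p = 1.72e-05, lost at adjusted p = 0.0675 with an estimated correlation). Serpina1e (2.17) and the complement component C8a (1.02) rose, while the elongase Elovl3 (-2.33) and the hydroxylase Cyp4a12b (-2.37) fell. Xenobiotic-metabolising enzymes had 7 of 23 lower and 1 higher, or 11 and 1 adjusted over the list alone (median -0.54, camera adjusted p = 1.01e-05, lost at adjusted p = 0.066 with an estimated correlation), with Cyp2c29 at -1.32 and Cyp2c37 at -1.88. Pericentral hepatocyte markers, which share Cyp2e1 and Cyp1a2 with that list, moved with them, with 1 of 11 lower, or 6 adjusted over the list alone (median -0.66, camera adjusted p = 0.000506, lost at adjusted p = 0.36 with an estimated correlation). Other large rises were Mt2 (4.17, SE 0.59), Mt1 (3.14), Gstp3 (3.80), C4a (3.43), the immunoglobulin segment Igkv9-120 (2.98) and Selenbp2 (2.83), which lost its call without 5 of 7 arrays (highest adjusted p 0.156, without WT HFD replicate 3). Other large falls were Cyp2c38 (-5.59), Cyp17a1 (-5.19), the lipocalin Obp2a (-4.78), Gdpd3 (-3.79), the transporter Slc22a27 (-3.57) and the tubulin Tubb2a (-2.86). For Mogat1, Fitm1 and Elovl3, 1 of the 4 TG arrays stood apart from the others.

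TG and WT on HFD differed in 791 genes, 373 higher and 418 lower in TG, of which 760 did not overlap between arrays. Over all genes 12.3% did not overlap, where chance gives 5.7% for 4 arrays against 3. The count was 401 without WT HFD replicate 1, 456 without WT HFD replicate 3, 297 without both WT HFD replicate 1 and TG HFD replicate 2, and 248 with the compared arrays alone. Between the diets, 106 genes were higher and 39 lower in TG on both, where independent lists would share 3.45 and 1.58, and 1 gene went opposite ways. These comparisons share no arrays, and the differences correlated across genes with r = 0.43, against 0 in simulated data.

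**Figure D2:**
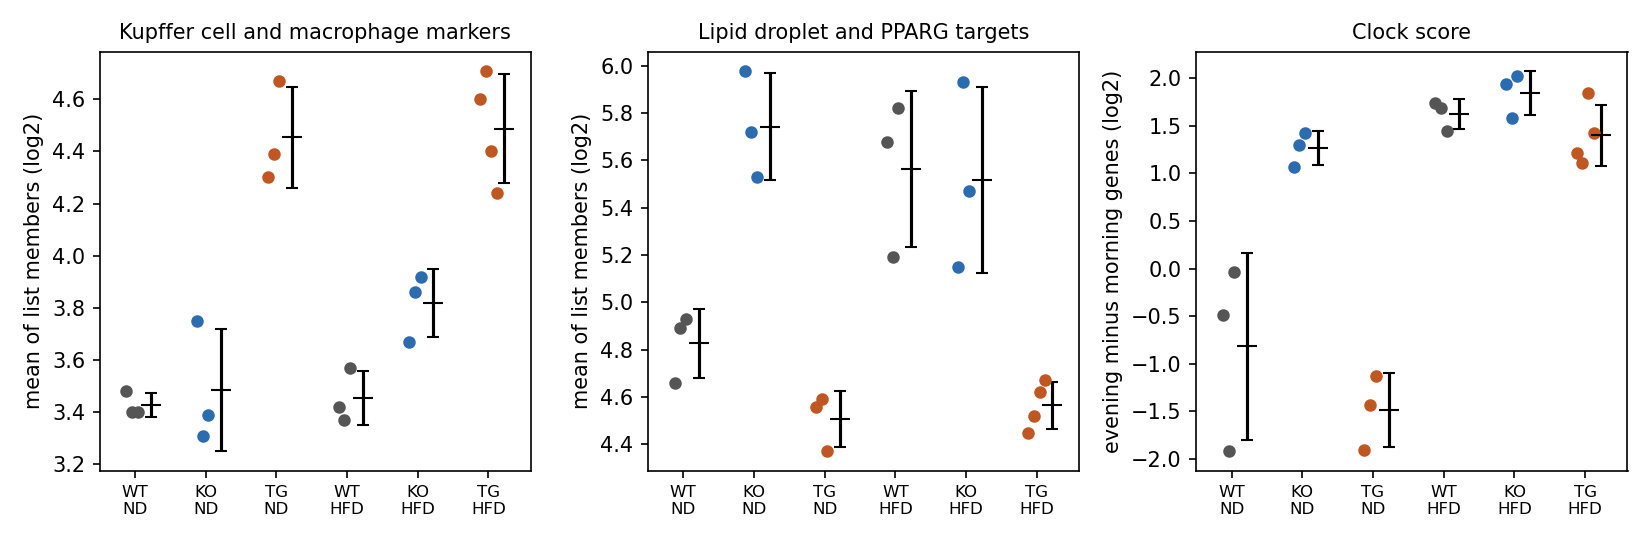
Mean log2 value per array of the Kupffer cell and macrophage markers and of the lipid droplet and PPARG targets, and the clock score (evening minus morning clock genes, log2), by genotype and diet, with the mean and SD of each group beside the points. The vertical axes do not start at 0, and the macrophage mean was 4.45 and 4.49 in the TG groups and between 3.43 and 3.82 in the others.

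The KO genotype was compared with WT next, first on the normal diet. Serpina1d and Serpina1e, members of the alpha-1-antitrypsin family of protease inhibitors, fell by 9.26 (SE 0.29, adjusted p = 1.14e-12) and 4.36 (SE 0.37, adjusted p = 1.4e-06). Of the lists of lipid metabolism 3 passed as higher in KO and cholesterol synthesis as lower. The phosphatidate phosphatase Lpin1 rose by 4.35 (SE 0.48), the lipid droplet protein Cidec by 3.50 (SE 0.63) and the lipogenic regulator Thrsp by 3.03 (SE 0.30). Of 19 lipid droplet genes 7 rose, or 9 adjusted over the list alone (median 0.66, camera adjusted p = 2.6e-06, lost at adjusted p = 0.15 with an estimated correlation), among them the apolipoprotein Apoa4 (1.83) and Mogat1 (1.76). Fatty acid and triglyceride synthesis had 3 of 24 genes higher, or 5 adjusted over the list alone (median 0.46, camera adjusted p = 7.6e-06, lost at adjusted p = 0.594 with an estimated correlation). Fatty acid oxidation had 2 of 31 higher, or 5 adjusted over the list alone (median 0.20, camera adjusted p = 0.00155, lost at adjusted p = 0.66 with an estimated correlation), with Acot3 at 3.08. Cholesterol synthesis had a median of -0.40 with no member past either adjustment (camera adjusted p = 0.0174, lost at adjusted p = 0.779 with an estimated correlation). It was also lost without 3 of 6 arrays (highest adjusted p 0.265, without WT ND replicate 3). Gluconeogenesis and glycogen genes had 5 of 13 higher, or 7 adjusted over the list alone (median 0.49, camera adjusted p = 7.6e-06, and adjusted p = 0.0352 with an estimated correlation). The glycogen synthase Gys2 (0.62) and Pck1 (0.91), an enzyme that commits carbon to glucose synthesis, were among them.

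Clock genes differed between KO and WT on ND, with 9 of 19 higher and 4 lower, and as many adjusted over the list alone (camera adjusted p = 9.17e-05, and adjusted p = 0.0145 with an estimated correlation). The deubiquitinase Usp2 (4.06, SE 0.26), the repressor Ciart (3.40) and the kinase Wee1 (3.22) rose, while Clock fell by 0.96. The clock score was 1.26 ± 0.18 in KO and -0.82 ± 0.98 in WT (SD, n = 3 each), a difference of 2.08 (two-sided exact permutation p = 0.1, the smallest that 3 arrays against 3 allow). This difference stood beside every gene group of the comparison. Heat-shock genes had 3 of 11 higher, or 4 adjusted over the list alone (median 0.29, camera adjusted p = 0.00155, lost at adjusted p = 0.258 with an estimated correlation). Dnajb1, Hspa1b and Hsph1 lost their calls without 6, 5 and 3 of 6 arrays (highest adjusted p 0.18, 0.108 and 0.0526). The other large rises were Mme (4.96), Gstp3 (4.79), Ctse (4.40) and Rgs16 (4.94), a regulator of G protein signalling. Mme and Ctse were also higher than in WT on ND in TG on ND (3.62 and 5.11) and in WT on HFD (4.66 and 6.51). Large falls were also seen for Asic5 (-2.96), the transcriptional repressor Bcl6 (-2.84), Cyp2c55 (-2.74), the retinol dehydrogenase Rdh16f2 (-2.66), Selenbp2 (-3.88) and the asparagine synthetase Asns (-3.02). Selenbp2 lost its call without KO ND replicate 2 (adjusted p = 0.0508), and Asns without each of the 6 arrays in turn (highest adjusted p 0.168, without WT ND replicate 1).

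KO and WT on ND differed in 661 genes, 307 higher and 354 lower in KO, of which 658 did not overlap between arrays. Of all genes 18.1% did not overlap, where chance gives 10%. The count was 377, 423 and 353 without WT ND replicate 2, WT ND replicate 3 and KO ND replicate 2. With the clock score as a covariate it was 31, the median absolute difference of the 661 genes stayed at 0.90, and their median SE rose from 0.18 to 0.33, since the score follows the groups.

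On the high-fat diet, Serpina1d (-8.14, SE 0.29, adjusted p = 1.08e-11) and Serpina1e (-2.28, SE 0.37, adjusted p = 0.00623) were again lower in KO, and Gstp3 was higher (3.20). Cyp17a1 fell by 5.85 (SE 0.69), As3mt, which methylates arsenic, by 2.54, and Tmem28 by 2.00. The female-biased Cyp2b13 rose by 3.27, Mug2 by 3.24 (SE 0.22), the water channel Aqp4 by 3.03 and the TRIM gene Trim12a by 2.77. Other large changes were lost in some repeats without 1 array: Trim30d (2.07) without 5 of 6 arrays, with a highest adjusted p of 0.132, Cyth4 (1.55) without 5 (0.112), Dsg1c (1.55) without 3 (0.0657), Cyp4a12b (-2.37) without 5 (0.125), Cyp2c55 (-1.84) without 3 (0.122) and Tc2n (-1.59) without 4 (0.0751).

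Lists of inflammatory cytokines (median 0.31, camera adjusted p = 1.65e-06), acute-phase proteins (0.48, 1.65e-06), extracellular matrix genes (0.25, 1.65e-06) and stellate cell and fibroblast markers (0.39, 1.99e-06) passed as higher in KO on HFD, with no single member past the test over all genes. Adjusted over the list alone 2, 0, 3 and 5 of their genes rose, and all 4 calls were lost with an estimated correlation (adjusted p = 0.0809, 0.685, 0.264 and 0.133 with an estimated correlation). The macrophage markers moved with them, with 1 of 24 rising, or 4 adjusted over the list alone (median 0.29, camera adjusted p = 6.49e-06, lost at adjusted p = 0.388 with an estimated correlation). That gene was Folr2 (1.30), which lost its call without 5 of 6 arrays (highest adjusted p 0.168). Cholesterol synthesis had a median of -0.30 and fatty acid oxidation one of -0.24 with no member past the test (camera adjusted p = 0.00161 and 3.15e-05). Both were lost with an estimated correlation (adjusted p = 0.75 and 0.685 with an estimated correlation), cholesterol synthesis also without 2 arrays (highest adjusted p 0.497, without KO HFD replicate 3) and fatty acid oxidation without WT HFD replicate 3 (adjusted p = 0.0747).

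In all, 75 genes differed between KO and WT on HFD, 43 higher and 32 lower in KO, and all 75 did not overlap between arrays. Over all genes 13.2% did not overlap, where chance gives 10%. The count was 43, 37 and 40 without WT HFD replicate 1, KO HFD replicate 1 and KO HFD replicate 2, and 37 with the compared arrays alone. Across the diets 11 genes were higher and 12 lower in KO on both, where independent lists would share 0.595 and 0.511, and 5 went opposite ways. The differences correlated across genes with r = 0.15, against 0 in simulated data, with no shared arrays.

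KO and TG were each compared with the same WT arrays. On ND 32 genes were higher and 37 lower than WT in both genotypes, against 2.84 and 1.34 for independent lists. On HFD the numbers were 20 and 16, against 0.723 and 0.603. Simulated data without effects shared 0 genes, but at most 0.15 genes per comparison were called there on average, so that this 0 does not measure sharing through common controls. The correlation across genes was 0.38 on ND and 0.47 on HFD, against 0.50 and 0.54 from shared controls alone, while the covariance was 0.0415 and 0.0429, against 0.0195 and 0.0194, a difference of 0.022 and 0.0235. With 3 WT arrays per diet the controls could not be split into groups of 2, and part of the excess may come from the shared controls.

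KO and TG were also set against each other. On ND the lipid droplet genes were higher in KO, with 9 of 19 rising and 1 falling, or 13 and 1 adjusted over the list alone (median 0.94, camera adjusted p = 5.23e-12, and adjusted p = 0.0166 with an estimated correlation): Cidec by 4.08 (SE 0.63), the perilipin Plin4 by 2.80, Apoa4 by 2.53 and Cd36 by 2.43. Gluconeogenesis and glycogen genes had 6 of 13 higher, or 7 adjusted over the list alone (median 0.66, camera adjusted p = 1.22e-07, and adjusted p = 0.0118 with an estimated correlation). Cholesterol synthesis was lower, with 7 of 19 falling, or 17 adjusted over the list alone (median -1.13, camera adjusted p = 1.11e-14, lost at adjusted p = 0.163 with an estimated correlation), including Sqle (-3.09) and the methyl sterol oxidase Msmo1 (-1.74). Macrophage markers had 11 of 24 lower in KO, or 16 adjusted over the list alone (median -0.92, camera adjusted p = 2.76e-15, and adjusted p = 0.0209 with an estimated correlation), with Marco at -4.97 (SE 0.39). With them moved interferon-response genes, 8 of 26 lower, or 16 adjusted over the list alone (median -0.59, camera adjusted p = 2.48e-12, and adjusted p = 0.0118 with an estimated correlation). T and NK cell markers had 2 of 18 lower, or 3 adjusted over the list alone (median -0.25, camera adjusted p = 0.0039, and adjusted p = 0.0247 with an estimated correlation). Of these markers Cd4 and Cd3g lost their calls without 3 and 4 of 6 arrays (highest adjusted p 0.0798 and 0.106).

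Clock genes differed here too, 9 of 19 higher and 4 lower in KO, or 11 and 5 adjusted over the list alone (camera adjusted p = 2.76e-06, and adjusted p = 0.00468 with an estimated correlation), with Usp2 at 3.63. The clock score differed by 2.75 (two-sided exact permutation p = 0.1, the smallest possible). Mfsd2a, a transporter of lysophospholipids, rose by 4.14, Lpin1 by 3.56 and Tcf24 by 3.54. Serpina1d (-9.26), Serpina1e (-4.41), Kcp (-3.53, SE 0.20, adjusted p = 5.33e-09) and Zfp872 (-3.78) fell, of which Zfp872 lost its call without 3 of 6 arrays (highest adjusted p 0.0817, without TG ND replicate 3). KO and TG on ND differed in 931 genes, 379 higher and 552 lower in KO, of which 923 did not overlap between arrays. The share over all genes was 21.1%, where chance gives 10%. The count was 568 without KO ND replicate 2, 615 without TG ND replicate 2 and 9 with the clock score as a covariate. There the median absolute difference of the 931 genes went from 0.91 to 0.88 and their median SE from 0.19 to 0.43.

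On HFD the lipid droplet genes Plin3 (1.46, SE 0.12, adjusted p = 1.62e-06), Vldlr (2.46), Cd36 (2.09) and Plin4 (1.97) were higher in KO than in TG. On that list 9 of 19 rose, or 11 rising and 2 falling adjusted over the list alone (median 1.21, camera adjusted p = 1.01e-09, lost at adjusted p = 0.0698 with an estimated correlation). Male-biased liver genes had 7 of 21 lower and 1 higher in KO, or 15 and 1 adjusted over the list alone (median -0.65, camera adjusted p = 1.69e-11, and adjusted p = 0.0198 with an estimated correlation). Serpina1e stood at -4.45 and the oxysterol hydroxylase Cyp7b1 at -1.40. Macrophage markers had 5 of 24 lower, or 14 lower and 1 higher adjusted over the list alone (median -0.60, camera adjusted p = 3.47e-10, lost at adjusted p = 0.141 with an estimated correlation). Marco stood at -3.05 and the haemoglobin scavenger receptor Cd163 at -2.90. The quinone reductase Nqo1 (1.79) and the insulin-like growth factor binding protein Igfbp2 (-2.39, SE 0.25) changed as well. Among the largest changes were Cyp2b9 (4.84), Slc22a27 (4.05), Mug2 (3.88), Cyp2c38 (3.59), Vnn1 (3.58), Serpina1d (-8.55) and Kcp (-3.65). KO and TG on HFD differed in 522 genes, 323 higher and 199 lower in KO, of which 509 did not overlap between arrays. The share over all genes was 12.1%, where chance gives 5.7%. The share higher was 61.9% and 51.7% after cyclic loess. The count was 309, 271 and 320 without KO HFD replicates 1, 2 and 3, 346 without both WT HFD replicate 1 and TG HFD replicate 2, and 156 with the compared arrays alone.

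**Figure D3:**
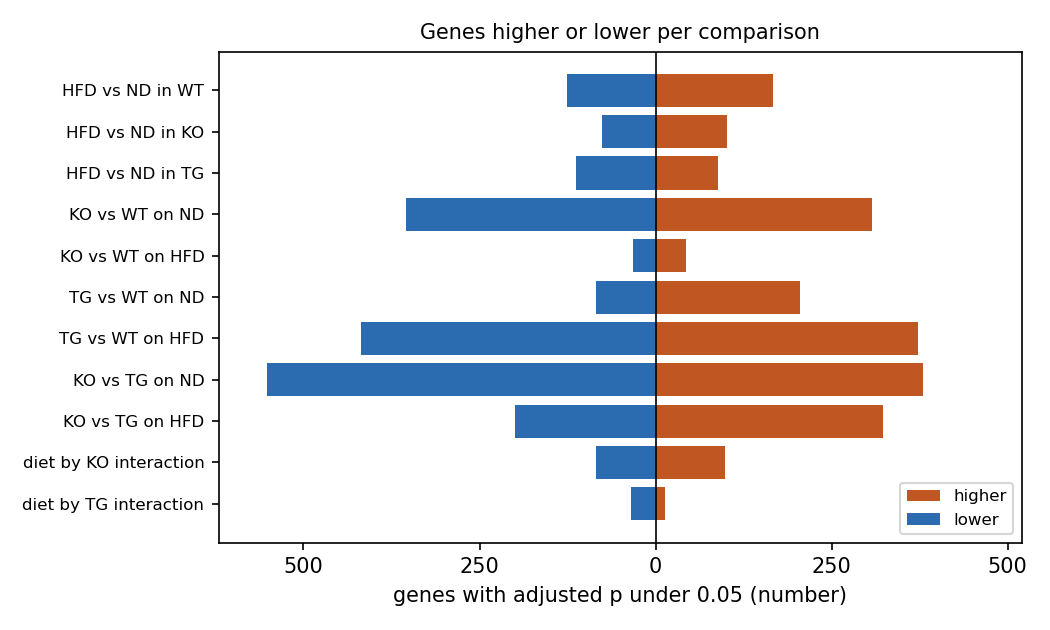
Number of genes with an adjusted p under 0.05 in each of the 9 comparisons and 2 interactions, higher to the right and lower to the left of 0. The counts run from 49 for the diet by TG interaction to 931 for KO against TG on ND.

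The effect of the diet was examined within each genotype, starting with WT. Ctse went from 1.83 ± 0.34 on ND to 8.34 ± 0.57 on HFD (SD, n = 3 each, SE 0.33, adjusted p = 3.41e-09). On ND, however, Ctse was also higher in KO (4.40) and TG (5.11) than in WT, so that WT on ND stood apart. Thrsp rose by 2.56 (SE 0.30), Apoa4 by 2.67 (SE 0.29), Acot3 by 3.05 (SE 0.52), Mogat1 by 2.26 and the lipoprotein receptor Vldlr by 2.01. Of 24 genes of fatty acid and triglyceride synthesis 3 rose, or 15 with 1 falling adjusted over the list alone (median 0.87, camera adjusted p = 1.4e-12, lost at adjusted p = 0.231 with an estimated correlation). Of 19 lipid droplet genes 5 rose, or 6 adjusted over the list alone (median 0.37, camera adjusted p = 0.000346, lost at adjusted p = 0.24 with an estimated correlation). Fatty acid oxidation had 4 of 31 higher, and as many adjusted over the list alone (median 0.14, camera adjusted p = 0.000517, lost at adjusted p = 0.595 with an estimated correlation). Cholesterol synthesis had a median of 0.60 with no member past either adjustment (camera adjusted p = 6.83e-06, lost at adjusted p = 0.473 with an estimated correlation). Among the genes fixed in advance, Cd36 (1.15), Cidec (2.90), the hormone Fgf21 (1.94) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (1.86), rose, and each lost its call without 5 of 6 arrays (highest adjusted p 0.162, 0.136, 0.156 and 0.0961). The others did not pass: Cidea 2.57, Fasn 1.77, Pparg 0.76, Col1a1 0.69, Scd1 0.20 and Tnf 0.12 (adjusted p = 0.115 for Fasn and higher for the rest).

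Male-biased liver genes were lower on HFD in WT, with 5 of 21 falling and 1 rising, or 9 and 1 adjusted over the list alone (median -0.54, camera adjusted p = 9.49e-09, and adjusted p = 0.033 with an estimated correlation). They included Selenbp2 (-4.78), the steroid dehydrogenase Hsd3b5 (-3.11) and Serpina1e (-2.20). Xenobiotic-metabolising enzymes had 8 of 23 lower and 1 higher, or 11 and 1 adjusted over the list alone (median -0.57, camera adjusted p = 1.52e-06, lost at adjusted p = 0.0673 with an estimated correlation). Cyp2c55 stood at -3.50, Cyp3a11 at -1.84 and the carboxylesterase Ces2a at -1.45. Clock genes changed, 8 of 19 higher and 2 lower, or 9 and 4 adjusted over the list alone (camera adjusted p = 0.000346, and adjusted p = 0.0323 with an estimated correlation): Wee1 rose by 3.06 (SE 0.34), Usp2 by 2.97 and Per3 by 1.85, and Arntl fell by 2.53. The clock score was higher by 2.44 on HFD (two-sided exact permutation p = 0.1, the smallest possible), beside the lipid lists above. Other large rises were Mme (4.66), the peroxisomal transporter Abcd2 (4.09), Gdpd3 (3.48), Slc22a27 (3.37), Mfsd2a (3.22), Rgs16 (3.23) and Cyp17a1 (3.16), and other large falls Clec2h (-3.69), Asic5 (-3.32), Mug2 (-3.12), the receptor Adgrf1 (-2.73) and Cyp2b10 (-3.05), a target of the xenobiotic receptor CAR. Rgs16, Cyp17a1 and Cyp2b10 each lost their call without 4 of 6 arrays (highest adjusted p 0.139, 0.134 and 0.1). Mme, Abcd2, Asic5, Mug2 and Cyp2c55 also differed from WT on ND in the same direction in KO and TG on ND.

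In WT 293 genes differed between the diets, 167 higher and 126 lower on HFD, of which 292 did not overlap between arrays. Over all genes 15.1% did not overlap, where chance gives 10%. The count was 195, 169, 166 and 179 without WT ND replicate 1, WT ND replicate 2, WT HFD replicate 1 and WT HFD replicate 3, 186 without both WT HFD replicate 1 and TG HFD replicate 2, and 139 with the compared arrays alone. With the clock score as a covariate it was 6, while the median absolute difference of the 293 genes went from 0.99 to 0.97 and their median SE from 0.19 to 0.40.

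In KO livers, of the xenobiotic-metabolising enzymes Cyp2b10 fell by 4.66 (SE 0.63, adjusted p = 0.00326), Cyp2c55 by 2.59, Cyp3a11 by 1.66 and Cyp2c29 by 1.06. In all 5 of 23 fell, or 7 falling and 1 rising adjusted over the list alone (median -0.20, camera adjusted p = 2.71e-06, lost at adjusted p = 0.0657 with an estimated correlation). Male-biased liver genes had 4 of 21 lower, or 13 adjusted over the list alone (median -0.70, camera adjusted p = 2.04e-11, and adjusted p = 0.0203 with an estimated correlation). Fatty acid oxidation had 2 of 31 lower, or 5 falling and 1 rising adjusted over the list alone (median -0.26, camera adjusted p = 0.00027, lost at adjusted p = 0.512 with an estimated correlation). Gluconeogenesis had 1 of 13 lower, or 4 adjusted over the list alone (median -0.39, camera adjusted p = 0.000309, lost at adjusted p = 0.0657 with an estimated correlation). That gene, Pck1 (-1.08), was lost without 2 of 6 arrays (highest adjusted p 0.0538). Inflammatory genes had 1 of 24 higher, or 5 adjusted over the list alone (median 0.53, camera adjusted p = 4.65e-05, lost at adjusted p = 0.0657 with an estimated correlation). The gene, Icam1 (1.29), encodes an adhesion molecule and was lost without 5 of 6 arrays (highest adjusted p 0.241). Macrophage markers had a median of 0.39 beside them, with no member past either adjustment (camera adjusted p = 4.65e-05, lost at adjusted p = 0.235 with an estimated correlation). Stellate cell and fibroblast markers had 1 of 18 higher, Reln (0.71, SE 0.10), or 2 adjusted over the list alone (median 0.43, camera adjusted p = 4.75e-06, lost at adjusted p = 0.0657 with an estimated correlation). Interferon-response (median 0.28) and antigen presentation genes (0.31) also passed as higher, with no single member past the test over all genes and 9 and 1 adjusted over the list alone (camera adjusted p = 3.41e-06 and 0.00129). Both were lost with an estimated correlation (adjusted p = 0.0691 and 0.235 with an estimated correlation), antigen presentation also without KO HFD replicate 1 (adjusted p = 0.132).

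The largest rises in KO that held without each array in turn were Cyp2b13 (3.38, SE 0.52), the kinase Camk1d (1.80) and the tight junction protein Cldn1 (1.49, SE 0.15). Most other large changes were lost without at least 1 array: Rdh16f2 (2.62) without 1 of 6, with a highest adjusted p of 0.0657, Gimd1 (1.47) without 2 (0.0791), Fkbp5 (-2.11) without 3 (0.0657), Slc22a27 (2.29) without 4 (0.118), Ugt2b38 (-2.56) without 4 (0.0997), and Lpin1 (-2.33) without 4 (0.152). Arrdc3 (1.97), Cenpm (1.42), the cytokine signal inhibitor Socs2 (-2.60), Cyp4a12b (-2.25) and Acot1 (-2.16) were lost without 5 (0.161, 0.146, 0.118, 0.103 and 0.141). None of the 10 diet genes fixed in advance passed in KO. The smallest adjusted p was that of Fgf21 (1.34, SE 0.44, adjusted p = 0.197), with Fasn at 0.95, Col1a1 at 0.48, Scd1 at -0.03, Tnf at -0.04, Cd36 at -0.20, Pparg at -0.27, Cyp7a1 at -0.54, Cidea at -1.14 and Cidec at -1.54.

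In KO 178 genes differed between the diets, 102 higher and 76 lower on HFD, none overlapping between arrays, and over all genes 17.1% did not overlap where chance gives 10%. The share higher was 57.3%, but 46.0% after cyclic loess and 40.5% with centred arrays. The count was 27, 40, 51, 65 and 85 without KO ND replicate 2, KO ND replicate 3, KO HFD replicate 1, KO HFD replicate 2 and KO HFD replicate 3, 62 with the compared arrays alone and 63 with the clock score as a covariate. The score differed by 0.58 (two-sided exact permutation p = 0.1, the smallest possible).

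In TG livers 5 of the 8 largest rises on HFD were clock genes. Ciart rose by 3.15 (SE 0.32), Wee1 by 3.09, Usp2 by 3.06 (SE 0.25, adjusted p = 2.04e-06), the transcription factor Dbp by 2.84 and Per3 by 2.47. Arntl fell by 2.49 and Npas2 by 2.67, the latter lost without TG ND replicate 1 (adjusted p = 0.0656). Of 19 clock genes 11 rose and 4 fell, or 11 and 5 adjusted over the list alone (camera adjusted p = 1.04e-08, and adjusted p = 0.000574 with an estimated correlation). The clock score was higher by 2.88 on HFD (two-sided exact permutation p = 0.029, the smallest that 4 arrays against 3 allow), and this stood beside the other groups. Xenobiotic-metabolising enzymes had 6 of 23 lower, or 9 falling and 1 rising adjusted over the list alone (median -0.42, camera adjusted p = 3.34e-11, and adjusted p = 0.0109 with an estimated correlation). Among them were Cyp2c55 at -2.31, Cyp3a11 at -2.20 and Cyp2c29 at -1.85 (SE 0.13). NRF2 antioxidant genes had 6 of 16 lower, or 7 adjusted over the list alone (median -0.35, camera adjusted p = 1.79e-05, lost at adjusted p = 0.081 with an estimated correlation), with the glutathione transferase Gsta4 at -0.78. Nqo1, Gstm1 and Abcc3 also passed but lost their calls without 6, 4 and 2 of 7 arrays (highest adjusted p 0.235, 0.175 and 0.118). Gluconeogenesis and glycogen genes had 3 of 13 higher, or 5 with 1 lower adjusted over the list alone (median 0.30, camera adjusted p = 5.95e-06, and adjusted p = 0.0219 with an estimated correlation), with Gys2 at 1.00 (SE 0.11). For Usp2, Elovl3, Cyp3a11 and Gys2, 1 of the 4 TG HFD arrays stood apart from the others.

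Cholesterol synthesis in TG had a median of -0.49 on HFD with no member past either adjustment (camera adjusted p = 4.07e-05, lost at adjusted p = 0.66 with an estimated correlation). The other largest changes were Mfsd2a (2.86), Rgs16 (2.79), Thrsp (2.26), Elovl3 (-3.54, SE 0.25), Csad (-3.19), an enzyme of taurine synthesis, Tubb2a (-2.65) and the dehydrogenase Dhrs9 (-2.60). Rgs16 lost its call without 6 of 7 arrays and Tubb2a without 2 (highest adjusted p 0.277 and 0.0716, both without TG ND replicate 1). None of the 10 diet genes fixed in advance passed in TG. Their values were 0.70 for Cidec (SE 0.59), with Fasn at 0.43, Cyp7a1 at 0.32, Fgf21 at 0.30, Cd36 at 0.14, Tnf at 0.03, Cidea at -0.05, Col1a1 at -0.16, Scd1 at -0.22 and Pparg at -0.95 (adjusted p = 0.255 for Pparg and higher for the rest).

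In TG 201 genes differed between the diets, 88 higher and 113 lower on HFD, of which 198 did not overlap between arrays, and over all genes 9.5% did not overlap where chance gives 5.7%. The share higher was 43.8%, but 56.5% after cyclic loess. The count was 73 without TG ND replicate 1, 96 without TG ND replicate 2 and 55 with the compared arrays alone. With the clock score as a covariate limma called 0 genes, with 1059 at an unadjusted p under 0.05 against 2234 without it, while the median absolute difference of the 201 genes went from 0.92 to 0.84 and their median SE from 0.17 to 0.41.

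The diet lists of the genotypes were then set against each other. WT and TG shared 29 genes higher and 29 lower on HFD, where independent lists would share 0.663 and 0.642, and 0 went opposite ways. WT and KO shared 9 and 8, against 0.768 and 0.432 for independent lists, with 3 opposite. KO and TG shared 2 and 4, against 0.405 and 0.387, with 11 opposite. The differences correlated across genes with r = 0.26, 0.06 and -0.03 in that order, against -0.01, 0 and 0 in simulated data, with no shared arrays. The rise on HFD in WT and the rise in KO over WT on ND share the WT ND arrays. In these, 76 genes were higher and 73 lower in both, against 2.31 and 2.01 for independent lists. Their covariance was 0.0648, against 0.0194 from the shared arrays alone, a difference of 0.0454 (r = 0.60 against 0.50). For the diet in WT and TG against WT on ND, the numbers were 24 and 23, against 1.54 and 0.477 for independent lists. The simulated counts were again 0, with the same limit. The covariance there was 0.0353, against 0.0194, a difference of 0.0159 (r = 0.36 against 0.50). The 3 shared arrays could not be split into groups of 2, and part of either excess may come from them. In all, 33 genes changed the same way relative to WT on ND in WT on HFD, KO on ND and TG on ND, 15 higher and 18 lower, among them Ctse, Mme, Asic5, Cyp2c55, Mug2 and Abcd2.

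Whether genotype altered the effect of the diet was tested by interactions. Relative to WT, the diet effect in KO differed most firmly for Mug2 (4.05, SE 0.30), Ctse (-5.27, SE 0.47), Usp2 (-4.01), Cldn1 (2.31), Mme (-5.11), Asic5 (2.42), the NAD-synthesis enzyme Nampt (-2.28) and the noncoding RNA Rian (2.44), with adjusted p of 0.000245 or lower. In TG it differed most firmly for Ctse (-6.51, SE 0.45), Asic5 (3.64), Mme (-4.22), the lipid transporter Abca3 (-1.70), Rian (2.07), the nucleotidase Nt5e (-2.38), Tmem260 (-1.02) and the insulin-degrading enzyme Ide (-0.89), with adjusted p of 0.00633 or lower. Of these, Mug2, Ctse, Mme, Asic5, Rian and Tmem260 were among the 33 genes that set WT on ND apart. Ctse, for example, differed from WT by 4.40 in KO and 5.11 in TG on ND, and by -0.87 and -1.40 on HFD. Gluconeogenesis genes had 1 of 13 lower in the KO interaction, or 6 adjusted over the list alone (median -0.57, camera adjusted p = 8.77e-06, and adjusted p = 0.0327 with an estimated correlation). Clock genes had 5 of 19 lower, or 4 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.000865, and adjusted p = 0.0327 with an estimated correlation). Cholesterol synthesis had a median of -1.04 in the TG interaction, with no member past the test and 5 lower adjusted over the list alone (camera adjusted p = 8.9e-12, lost at adjusted p = 0.677 with an estimated correlation).

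The KO interaction took in 183 genes, 99 higher and 84 lower, or 54.1% higher against 43.2% with centred arrays, and the TG interaction 49 genes, 14 higher and 35 lower. The KO count was 108, 88, 94, 105 and 112 without WT ND replicate 2, KO ND replicate 2, WT HFD replicate 3, KO HFD replicate 1 and KO HFD replicate 3, and 19 with the clock score as a covariate. The TG count was 32, 22 and 23 without WT ND replicates 1, 2 and 3, and 22, 31 and 27 without TG ND replicates 1, 2 and 3. It was 24 without WT HFD replicate 1, 32 without both WT HFD replicate 1 and TG HFD replicate 2, and 29 with the clock score as a covariate.

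Signalling by BMP and TGF-beta was examined through fixed lists and genes. The 28 BMP ligands, receptors and SMADs passed in no comparison, with a lowest camera adjusted p of 0.123 (KO against TG on ND, median -0.15), nor did the 20 BMP targets, with a lowest of 0.0984 (TG against WT on ND, median -0.16). Single members did pass, 9 times over all comparisons for the first list and 5 times for the second, and are named here after their values were seen. The receptor gene Tgfbr2, one of the 33 genes that set WT on ND apart, was higher than in WT on ND in KO (0.80), TG (1.04) and WT on HFD (1.22), with a KO interaction of -1.07. Bmp7 stood at -1.20 for TG against WT on HFD, 1.30 for KO against TG on ND and -1.96 in the KO interaction, and Hjv at 0.65 for the diet in KO and 0.54 for KO against TG on HFD. Id2 was lower in KO than in WT (-1.22, SE 0.23) and than in TG on ND, while the diet calls were Id3 in WT (-0.88), Smad9 in KO (-1.85) and Hamp2 in TG (2.04). Without 1 array at a time only Id2 for KO against WT and Tgfbr2 for TG against WT on ND and the diet in WT held, and the highest adjusted p of the others ran from 0.0665 to 0.231. Adjusted over the list alone, KO against WT on ND had 2 higher and 2 lower of the 28 and 1 higher and 2 lower of the 20, and TG against WT 2 higher on ND and 1 each way on HFD of the 28 and 0 of the 20. TGF-beta and activin targets passed for TG against WT on ND alone, with 2 of 28 higher over all genes and over the list alone (median 0.25, camera adjusted p = 0.00935, lost at adjusted p = 0.124 with an estimated correlation). These were the matrix protein Tgfbi (0.90, SE 0.13, adjusted p = 0.000983) and the activin subunit Inhba (1.48, SE 0.23, adjusted p = 0.00188). Tgfbi was also among the 33 genes that set WT on ND apart from the other groups named. The BMP target Id1 did not pass in any genotype comparison, at -0.05 and -0.30 for KO and -0.27 and -0.17 for TG against WT on ND and HFD. Hamp, the iron hormone induced by BMP signals, was at -0.20, 0.17, -0.16 and -0.31 in the same order, and the inhibitory Smad7 at -0.13, -0.28, -0.19 and -0.52 (SE 0.19, adjusted p = 0.153 for the last and higher for the others). KO against TG gave 0.23 and -0.13 for Id1, -0.04 and 0.48 for Hamp and 0.06 and 0.24 for Smad7 on ND and HFD, with adjusted p of 0.398 or higher.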

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

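The tests of neighbouring genes and of other splits of the samples were set before their results were seen, while those of clock phase, array quartiles, cell types and the clock score were chosen only after the result was seen.

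A group of 33 genes set WT on ND apart from WT on HFD, KO on ND and TG on ND, 15 higher and 18 lower. Harvest of the WT ND animals at another clock phase would set the others apart from them alike, and is argued against by a clock score that differed by 2.44 in WT on HFD and 2.08 in KO on ND, but -0.67 (SE 0.38) in TG on ND. Genetic background may account for part of the pattern: 7 members had another member among the 10 tested genes on either side, where 1000 random sets of like expression had a median of 0 and a 95th percentile of 4 (one-sided permutation p = 0.002). The 7 lie at 2 places, Rian with AF357425, AF357355 and DQ267102, and Mug2 with Gm10319 and Mug-ps1, so that shared transcripts or probes of near-identical copies stay open for them. Quartiles, which normalization evens out, do not decide on array or RNA quality (1 WT ND array lay just outside the range of the other 16), and the mean correlations of these arrays with other groups (0.9699 to 0.9709) lay within the range of the rest (0.9633 to 0.9727) and show no poor array, but RNA handling and cohort cannot be told apart from the group.

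Macrophage markers were higher in TG on both diets, with medians of 1.14 (95% bootstrap interval 0.39 to 1.51, 2000 draws) and 1.18 (0.44 to 1.42). A lower share of hepatocytes would raise endothelial, stellate and cholangiocyte markers alike, but the higher of the upper 95% bounds of their pooled median was 0.26, below both intervals (stellate markers alone had medians of 0.35 and 0.31). Blood, or an influx of lymphocytes and neutrophils, would raise T, NK, B and neutrophil markers alike, and the higher upper bound there was 0.38, also below both. Other lists were bounded only in pools and may be dimmer, so neither source is excluded. No list marks monocytes apart from macrophages, so that their entry was not tested and stays open. The intervals come from drawing genes, not animals, and do not measure the spread between animals. More macrophages, more RNA per macrophage and an effect of the TG genotype on either stay open as hypotheses and were not tested.

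The clock score was -0.82 ± 0.98 in WT, 1.26 ± 0.18 in KO and -1.48 ± 0.39 in TG on ND. It was 1.63 ± 0.16, 1.85 ± 0.24 and 1.40 ± 0.32 on HFD (SD, n = 3, and 4 for TG on HFD). A diet effect alike in every genotype is argued against by changes of 0.58 in KO and 2.88 in TG (SE 0.38 and 0.35). A KO effect alike on both diets (2.08 on ND, 0.22 on HFD) is undecided, as WT on ND varied most. Harvest at different times of day may have given the pattern, as the morning clock genes differed by -0.90 between KO and WT on ND while the evening genes were higher. A diet effect that depends on genotype would look the same and cannot be told apart from it, as the labels give no harvest time.

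In TG on HFD, the only group of 4, 14 of 192 named genes had 1 array apart from the other 3. The gap as a share of the group's range was above 0.829, which chance gives in about 1 of 20 genes. Many of the 14 may thus be due to chance. The share has no scale, so that small gaps pass too, as for Rps28 (5.93 against 6.04 to 6.05) and Mogat1 (1.05 against 0.83 to 0.84). The array was replicate 2 for S100a8 (0.971), Ltf (0.955), Lect2 (0.863), Elovl3 (0.861), Fitm1 (0.847) and Retnlg (0.829, at the limit). It was replicate 1 for Usp2 (0.922), Rps28 (0.889) and Cyp3a11 (0.843), replicate 3 for Fmo2 (0.877), and replicate 4 for Mogat1 (0.959), Cyp3a44 (0.944), Mup20 (0.871) and Gys2 (0.838).

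The diet effect in KO differed from that in WT in 183 genes, a number that 5 of 100 splits reached, the highest other split giving 255. In TG it differed in 49 genes, reached by 3 of 100 splits, and the highest other split gave 686 genes. These splits exchange genotypes within a diet and so carry genotype effects into the interaction, which makes them no test of chance for it. The genes with the smallest p were Mug2 (4.05), Ctse (-5.27), Usp2 (-4.01), Cldn1 (2.31), Mme (-5.11), Asic5 (2.42), Nampt (-2.28) and Rian (2.44) for KO. For TG they were Ctse (-6.51), Asic5 (3.64), Mme (-4.22), Abca3 (-1.70), Rian (2.07), Nt5e (-2.38), Tmem260 (-1.02) and Ide (-0.89).

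The same difference was found for 13 lists in KO. Lower were fatty acid synthesis (camera adjusted p = 0.000146), fatty acid oxidation (1.93e-07), lipid droplet (0.000398), gluconeogenesis (8.77e-06), glycolysis (0.00234), circadian clock (0.000865) and heat-shock genes (0.00208). Higher were inflammatory (0.000865), interferon (0.00179) and extracellular matrix genes (0.0271) and the macrophage (0.0325), endothelial (0.0108) and stellate cell markers (0.00343). In TG it was found for 6 lists, lower for fatty acid synthesis (0.000159), cholesterol synthesis (8.9e-12), fatty acid oxidation (0.0145), lipid droplet genes (0.00418) and pericentral markers (0.0164), and higher for male-biased genes (0.0374). With an estimated correlation 2 of these 19 calls held, gluconeogenesis and the circadian clock in KO (adjusted p = 0.0327 with an estimated correlation for each). Without 1 array at a time the highest adjusted p was 0.165 for extracellular matrix and macrophage lists and 0.103 for endothelial markers in KO. It was 0.31, 0.0644, 0.176 and 0.234 for fatty acid oxidation, lipid droplet, male-biased and pericentral lists in TG.

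Splits of the same arrays into groups of the same sizes were also counted for each comparison. For the diet in TG, TG against WT on HFD and KO against TG on HFD, the real split gave 201, 791 and 522 genes. The highest other gave 44, 252 and 158. Only the real split reached its count (1 of 35 each, the lowest possible, unadjusted). For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real split and the highest other gave 293 and 2 for the diet in WT, and 178 and 2 for the diet in KO. They gave 661 and 0 for KO against WT on ND, 75 and 0 on HFD, 289 and 0 for TG against WT on ND and 931 and 1 for KO against TG on ND.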

How the results depend on the processing

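The repeats without both arrays that stand apart (WT HFD replicate 1 and TG HFD replicate 2) and with the clock score as a covariate were chosen only after the data had been seen; all others were planned. Under cyclic loess, centred arrays, the dimmest 40% of genes left out, the trended and robust prior, array weights and the mean of all probe sets, all 11 counts stayed within 1.5 times the main value, and no named gene turned its direction. Lists were repeated only with the first 3 of these settings, where none turned. Of 159 list calls 23 held with an estimated correlation, 149 after loess, 158 with centred arrays, 131 without the dimmest genes and 135 without both arrays, and 98 held without every array in turn; of 361 named calls of genes 222 did. Precision is limited by 3 or 4 animals per group and by the 12523 genes with a mean log2 value below 2, near background. No paired analysis was possible because animal numbers are not shared between groups. Sex was not run as a covariate because all animals were of 1 sex, and the alternative of other Kcp probe sets gave no value because Kcp has 1 probe set. The cause was not tested for any value below unless stated.

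With the compared arrays alone, which leave fewer residual degrees of freedom, the counts that moved were 139 for the diet in WT, 62 in KO and 55 in TG. They were 37 for KO against WT on HFD, 248 for TG against WT on HFD and 156 for KO against TG on HFD. Without both arrays that stand apart they were 186 for the diet in WT, 297 for TG against WT on HFD, 346 for KO against TG on HFD and 32 for the diet by TG interaction. The differences of Cd36 (-0.09) and Cidea (0.01) for the diet in TG and of Hamp (-0.10) for KO against WT on HFD, none of them past the test, turned sign there.

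With the clock score as a covariate the counts were 6 for the diet in WT, 63 in KO and 0 in TG (limma, with 1059 at an unadjusted p under 0.05). They were 31 for KO against WT and 170 for TG against WT on ND, 9 for KO against TG on ND, and 19 and 29 for the interactions in KO and TG. The score follows the groups, so that standard errors grew while most differences stayed: over the genes called for KO against TG on ND the median SE went from 0.19 to 0.43 and the median absolute difference from 0.91 to 0.88. Of all called genes 292 of 293 kept their sign for the diet in WT, 193 of 201 in TG, 657 of 661 for KO against WT on ND and 917 of 931 for KO against TG on ND, and in the other comparisons every one did. Among the called genes taken by the naming rule, Npas2 for the diet in TG (1.17), a clock gene, and Cd4 for KO against TG on ND (0, rounded) turned sign. Sign also turned for genes that had not passed: Slc1a2 (-0.03) and Scd1 (-0.08) for the diet in WT, Tnf (0, rounded) in KO, and Atf4 (0.18), Gpr182 (0.07), Cidea (2.44) and Col1a1 (0.69) in TG. For KO against WT on ND it turned for Kcp (0.03), Id1 (0.02) and Smad7 (0.21). For KO against TG on ND it turned for Col14a1 (0.01), Cox5a (-0.12), Atp6v0d2 (0.58), Rgs5 (0.10) and Hamp (0.05).

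Without 1 array at a time the counts ran from 166 to 295 for the diet in WT, 27 to 159 in KO and 73 to 182 in TG. They ran from 353 to 494 for KO against WT on ND, 37 to 73 on HFD, 165 to 226 for TG against WT on ND, and 401 to 865 on HFD. The range was 568 to 783 for KO against TG on ND and 271 to 598 on HFD, and 88 to 189 and 22 to 67 for the interactions in KO and TG. Leaving out 1 array lowers the number of animals, and most counts fell. The genes whose difference turned sign had not passed. In the diet comparisons they were Scd1 (-0.21 to 0.16) and Tnf (-0.26 to 0.27) in KO, and Cd36 (-0.09 to 0.35), Cidea (-0.10 to 0.01), Fasn (-0.05 to 0.75) and Tnf (-0.10 to 0.29) in TG. Between genotypes they were Id1 (-0.18 to 0.03) and Smad7 (-0.25 to 0.04) for KO against WT on ND and Hamp (-0.10 to 0.32) for KO against WT on HFD. They were further Id1 (-0.34 to 0.06) for TG against WT on HFD, Smad7 (-0.05 to 0.16) for KO against TG on ND and Id1 (-0.30 to 0.01) for KO against TG on HFD. The list of fatty acid and triglyceride synthesis in the TG diet comparison, which had passed, had a camera adjusted p from 0.000173 to 0.995 and turned direction without TG HFD replicate 3.

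At an adjusted p of 0.10 the genes shared in the same direction rose from 145 to 223 for TG against WT on ND and HFD, 69 to 122 for KO and TG against WT on ND, and 36 to 61 on HFD. For the diet they rose from 17 to 43 in WT and KO and 6 to 13 in KO and TG (opposite 11 to 27). For the diet in WT they rose from 149 to 246 with KO against WT on ND and 47 to 77 with TG against WT on ND, since longer lists share more. The other 2 overlaps stayed within 1.5 times (23 to 33 and 58 to 85).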

Other observations

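None of the tests in this part was chosen after its result was seen; Nnt, Rpl3 and the probe sets without a name were picked out afterwards. Some gene groups outside the main themes passed for TG against WT, and each of these calls was lost with an estimated correlation. Cytosolic ribosomal protein genes had a small positive median in TG against WT, 0.13 on ND and 0.17 on HFD (camera adjusted p = 0.000345 and 5.14e-05), and with an estimated correlation both were lost (adjusted p = 0.157 and 0.0823 with an estimated correlation). The member Rpl3 rose by 3.09 and 1.21, alone among 25 members on either diet, but it was also higher in KO than in WT (2.47 and 1.05) and in WT on HFD than on ND (1.83), and is among the 33 genes that set WT on ND apart. Immediate-early genes had 2 of 21 higher in TG on HFD, Egr1 (2.38) and Fos (0.77) (median 0.36, camera adjusted p = 0.00875, lost at adjusted p = 0.186 with an estimated correlation). Egr1 lost its call without WT HFD replicate 1 (adjusted p = 0.0864) and Fos without 5 of 7 arrays (highest adjusted p 0.105). Genes of the insulin and IGF axis had 1 of 20 higher in TG on HFD, Igfbp2 (2.09, SE 0.25), with a median of 0.12 (camera adjusted p = 0.0173, lost at adjusted p = 0.26 with an estimated correlation and at 0.0909 without TG HFD replicate 1).

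Lists that passed in no comparison, with their lowest camera adjusted p, were iron metabolism (0.185), lipoproteins and apolipoproteins (0.32) and the markers of adipocytes (0.188), cholangiocytes (0.0766), kidney and mesothelium (0.0764), pancreatic acinar cells (0.162) and skeletal muscle (0.4). The erythroid list had 4 measured genes and was not tested. Among 17824 probe sets without a single gene name, fitted on their own, 92 differed between KO and WT on ND, 80 between KO and TG on ND, 51 between TG and WT on HFD and 14 between KO and WT on HFD.

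That genetic background near the targeted gene may underlie genes that differ in KO was tested as a hypothesis. Of 11 genes that set KO apart on both diets, 2, Serpina1d and Serpina1e, had another member among the 10 tested genes on either side, at the 95th percentile of 2 of the random sets (one-sided permutation p = 0.054). Both are copies of 1 family, and with 1 gene kept per name stem 0 of 10 had a neighbour, against a 95th percentile of 0. Of the 100 tested genes on either side of Kcp 0 were members. With so few genes neither test decides, and background cannot be told apart from the genotype. Over all genes, 3 of those 200 flanking genes differed between KO and WT on ND and 0 on HFD, where 6 and 0.7 would by chance (limma).

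For the 49 genes that set TG apart on both diets, 34 higher and 15 lower, 0 members had a neighbour among them. Random sets had a median of 2 and a 95th percentile of 6. This argues against linked background as the common source of the set, but cannot do so for a single gene that differs without its neighbours. Nnt, a mitochondrial transhydrogenase that the C57BL/6J strain carries in a truncated form, was higher than in WT on ND by 1.17 in WT on HFD, 1.17 in KO on ND and 0.92 in TG on ND. Strain is not given in the labels, and whether a difference of background may lie behind this value was not tested beyond the 7 neighbouring genes reported for WT on ND.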
